A study of Mus musculus with 32 samples.

How the data were processed

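RNA-seq libraries of total RNA, 8 of NSC carrying 4 culture numbers, 8 of PM-NSC and 16 of glioblastomas, sequenced on a HiSeq2000 per the labels, were read from gene-level and transcript-level tables. The values are FPKM that the authors deposited. Per the submitters' processing notes, reads were aligned to mm10 with TopHat2 2.0.8 and assembled into FPKM with Cufflinks 2.2.1. Nothing in the files gives read counts, so the depth of each library is unknown, and no sum of FPKM can stand in for it. The 3 tables hold 46855 genes each and were made separately for NSC, PM-NSC and tumors. Every column was matched to a sample by its name, and 0 columns had no sample. Of the gene identifiers, 46366 are in GENCODE M21, which gave biotypes, and 35622 loci equal those there once the start, which the files count from 0, is shifted by 1 (149 as written). No QKI protein or exon-level value is in the files.

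Values were used as log2(FPKM + 1). A gene was tested when it reached 1 FPKM in at least 4 libraries in PM-NSC or 2 in NSC, which left 13555 and 14077 genes. Each table was fitted separately with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were QPP against PP (4 against 4), labelled QKI-null NSC against the mean of the other 3 NSC groups (2 against 6), 4OHT against EtOH within floxed and within wild-type NSC (2 against 2 each), and the difference of those 2 changes. The difference between the PM-NSC change and the NSC change was tested on the genes measured in both. Unlike the other comparisons, it used 1 fit of the NSC and PM-NSC libraries together, so its SE pools the spread of both tables. The 2 changes have no library in common. The tumors have no control group, so their levels were described and 12 correlations between list scores or genes were tested with 100000 permutations (seed 79). The expected overlap of 2 gene sets was the product of their sizes over the genes tested in both. Groups, comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

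The rule named, for each comparison, up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold, with a mean of 5 FPKM or more in the higher group and groups that do not overlap. It left out predicted and clone-named genes, microRNAs, small nucleolar RNAs, pseudogenes and sex-linked controls. It added Qk, Pten and Trp53, up to 4 members per gene list by smallest p (by highest median in tumors), the 5 genes with the smallest p for transcript usage with any reported QKI target that passed, and the 8 genes with the largest SD across tumors. Transcript proportions were tested with limma's diffSplice on log2 transcript values (minimum 1 FPKM in the same number of libraries), with Simes' method per gene, and shares are a transcript's FPKM over the sum of its gene's. Reported QKI targets were counted among genes with changed transcript proportions with Fisher's exact test. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, for lists with at least 5 measured genes: 22 lists in PM-NSC and 21 in NSC. Camera at the preset correlation called 5 and 7 of these. With an estimated correlation it called 0 of 22 in PM-NSC (lowest adjusted p = 0.926) and 0 of 21 in NSC (0.62). Fry in 1 direction called 0 in PM-NSC (lowest adjusted p = 0.20) and 0 in NSC (0.137), and fry for change in either direction called 12 and 15. In the comparisons of labelled QKI-null libraries, genes at an unadjusted p under 0.05 numbered 2711 in PM-NSC and 2289 in NSC, and 1771, 146 and 709 in floxed NSC with 4OHT, wild-type NSC with 4OHT and their difference.

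The NSC titles carry culture numbers that occur in both treatments (2 and 9 in wild type, 3 and 5 in floxed), which would pair a culture's EtOH and 4OHT libraries. After the group means were removed, the paired libraries correlated at 0.325 (wild type) and 0.176 (floxed), and limma's duplicateCorrelation gave 0.278. The unpaired fit is the main one and the fit with culture as a block is given beside it where it changed a call or moved a count by over 1.5 times. The labels do not say whether libraries with different numbers came from different animals, so p-values describe no more than the spread between cultures. In the unpaired NSC fits the 2 libraries of a culture number count as separate cultures. A label places QKI loss in libraries where the Qk gene level was higher, so the wording "labelled QKI-null" is used throughout.

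The tests were tried on simulated data built from the same tables. Changed genes and switched transcripts were drawn at a mean log2 level above 2, and each library varied independently of the others. The real PP libraries fell into 2 pairs and the NSC titles repeat culture numbers. The rates below may therefore not hold for the real designs or for lower genes. With 13555 genes in the PM-NSC design, added log2 changes of 0.5, 1 and 2 were recovered for 28%, 74% and 94% of genes and -1 for 84%, with 4.1% of calls false. In the NSC design with 2 against 6 libraries these were 8%, 66%, 96% and 66%, with 1.7% false. With 2 against 2 in floxed cultures they were 0%, 38%, 90% and 44%, with 5.5% false, and for the difference of changes 0%, 14%, 54% and 4%, with 0% false. The shifted list was called and 0 of 20 other lists. These lists were random genes simulated to vary independently, while the estimated correlation of the lysosome list in PM-NSC was 0.568. The simulation therefore cannot show how often camera calls a list of correlated genes falsely. Of 200 genes with a switched transcript 191 were recovered (95.5%), with 10.7% of calls false. A correlation over 16 tumors reached p under 0.05 in 5.5% of simulations with a true value of 0, 50% at 0.5 and 98.5% at 0.8.

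The alternatives were a pseudocount of 0.1, no filter on low values, a minimum of 5 FPKM, quantile scaling, eBayes without a trend, leaving out each library, the culture block, the culture as a random effect, NSC fitted as 2 groups or compared with 4OHT-treated wild type alone, transcript minimums of 0.1 and 5 FPKM, an F test per gene for transcripts, and, for tumors, z-scored lists and leaving out the 2 tumors farthest from the median. After the data were seen, each pair of PP libraries that correlated most closely was also used alone as the control of QPP. Picking pairs for their closeness lowers the spread between controls, so counts and p-values against a pair are biased toward calls. Other programs used were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Small RNAs were kept in the tests, and the main count of each comparison is given with its number of protein-coding genes. In the called lists of PM-NSC and of NSC against the other 6 libraries, median, mean and camera had the same sign. Pseudogenes can share reads with their parent genes in such tables, and the strand of the libraries is not given.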

Results

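RNA-seq levels were compared in 32 mouse libraries of 3 kinds, all from animals or cultures carrying Nestin-CreERT2, a Cre recombinase active in Nestin-expressing neural cells once 4OHT, a tamoxifen metabolite, is given. The gene of interest was Qk, which encodes QKI, an RNA-binding protein of the STAR family with a known role in splicing. The neural stem cells (NSC) came from the subventricular zone of newborn pups and made 4 groups of 2 libraries: wild type with ethanol (EtOH), wild type with 4OHT, floxed Qk with EtOH, and floxed Qk with 4OHT, the last labelled QKI-null. The pre-malignant neural stem cells (PM-NSC) made 2 groups of 4 libraries, PP (labelled null for Pten and p53) and QPP (labelled null for QKI as well), all treated with 4OHT. The 16 glioblastomas came from QPP mice given tamoxifen as pups. Values were FPKM, a length- and library-scaled fragment measure, so the depth of each library is unknown and no counting interval can be given. Between 12878 and 15031 genes reached 1 FPKM per library. Small RNAs took 31.19% to 36.42% of all FPKM in NSC, 79.81% to 87.86% in PM-NSC and 92.08% to 96.5% in tumors, so levels set side by side across the 3 tables are not tested differences.

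In both cell systems the Qk gene (ENSMUSG00000062078, mm10 chromosome 17, 10206471 to 10319361) was higher at gene level where the labels say QKI-null. In PM-NSC it was 170 ± 29.2 FPKM (SD, n = 4) in PP and 300.4 ± 18.2 (SD, n = 4) in QPP, a log2 change of 0.83 ± 0.13 (SE) with adjusted p = 0.0137. In NSC it was 562 ± 43.9 FPKM (SD, n = 2) in the labelled QKI-null cultures, against 313 ± 2.8 and 323 ± 9.6 in wild type with 4OHT and EtOH and 278 ± 41.7 in floxed cultures with EtOH (n = 2 each), a log2 change of 0.88 ± 0.16 with adjusted p = 0.0414 against the other 6 libraries. The rise lay in 1 transcript while another fell. ENSMUST00000042296 (10210179 to 10319361) made up 62.6% ± 5.89 of Qk FPKM in PP (SD, n = 4) and 2.12% ± 0.0996 in QPP, and 65.5%, 66.5% and 63.6% in the 3 NSC control groups against 2.26% ± 0.0887 (SD, n = 2) in the labelled QKI-null cultures. ENSMUST00000097414, which spans the same positions as the gene, went from 62.3 ± 1.97 FPKM in PP to 294 ± 17.7 in QPP. The labels do not say which exon the floxed allele lacks after recombination. Pten and Trp53 gene levels did not pass the test in PM-NSC (log2 -0.02 ± 0.07, adjusted p = 0.924, and 0.16, adjusted p = 0.599), where both groups carry the same alleles of these genes per the labels, nor in NSC (0.18, adjusted p = 0.594, and 0.21, adjusted p = 0.57). In NSC the Qk call was made by limma over 14077 genes. Against wild type with 4OHT alone Qk was at 0.84 with adjusted p = 0.11, which ends the call, and it also ended with no filter on low values (0.104), without QKI-null culture 3 (0.282) or 5 (0.471), and without wild-type 4OHT culture 2 (0.127) or 9 (0.121) or EtOH culture 2 (0.0793) or 9 (0.0705).

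**Figure D1:**
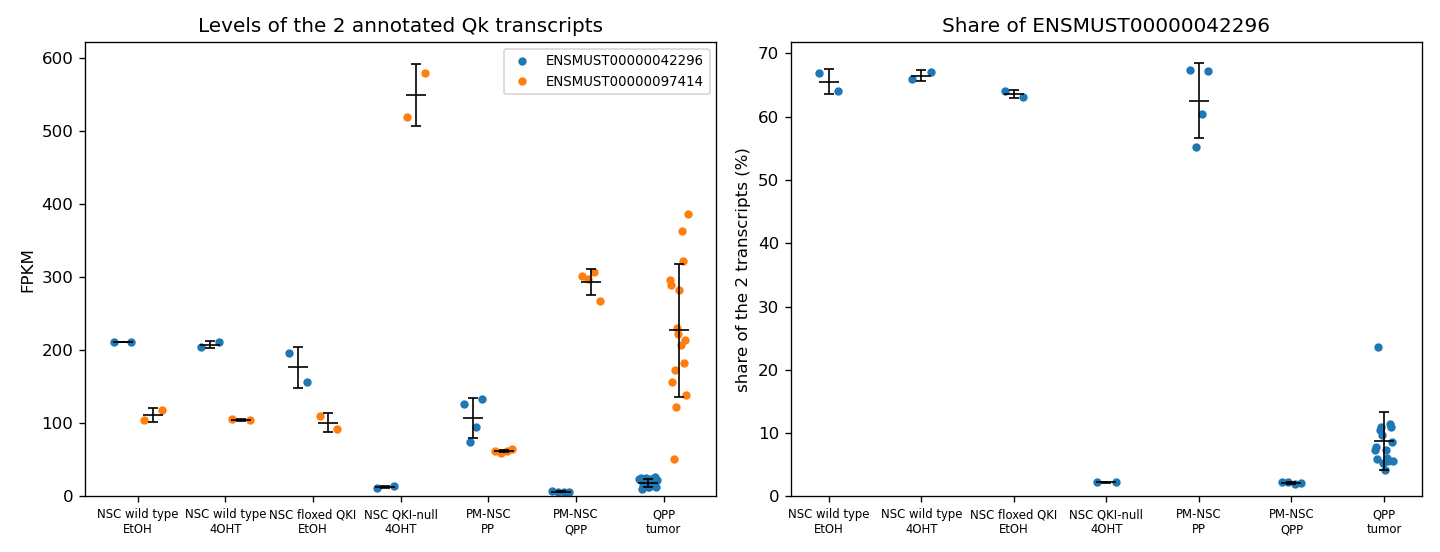
FPKM of the 2 Qk transcripts (left) and the share of ENSMUST00000042296 in their sum (right) in each library, by group, with group means and SD as error bars. ENSMUST00000042296 averages 107 in PP and 6.36 in QPP, while ENSMUST00000097414 averages 62.3 and 294.

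The question in PM-NSC was what differs in cells lacking Pten and p53 when they are labelled QKI-null as well. Plcb4, a phospholipase C, had the largest rise among the named genes, from 2.30 FPKM in PP to 10.6 in QPP (log2 1.82 ± 0.10, SE, n = 4 per group, adjusted p = 0.000121; chromosome 2, 135741830 to 136014593). Dclk1, a doublecortin-like kinase, rose from 61.1 to 138.6 FPKM (log2 1.17 ± 0.12, adjusted p = 0.00317), and Nucb2, the precursor of nesfatin, rose by 1.35 ± 0.20 (adjusted p = 0.0132). Necap2, which takes part in clathrin-mediated endocytosis, fell by 2.02 ± 0.20 on the log2 scale, from 34 to 7.33 FPKM (adjusted p = 0.00295; chromosome 4, 141066512 to 141078357). Cald1, the actin-binding protein caldesmon, fell by 1.88 ± 0.12, from 19.8 to 4.63 FPKM (adjusted p = 0.000278; chromosome 6, 34598500 to 34775473), and Mlc1, an astrocyte membrane protein, fell from 98.8 to 27.2 FPKM (log2 -1.83 ± 0.22, adjusted p = 0.00595). The other risen genes named by the rule were Wfdc2 (1.28), Tub (1.2), Azin2 (1.2), Pnp2 (1.14) and Brsk2 (1.14), with adjusted p from 0.0115 to 0.0331. The other fallen ones were L3hypdh (-1.92), the prolyl isomerase Fkbp7 (-1.92), the unconventional myosin Myo9b (-1.66), the dystrophin-complex member Sspn (-1.64) and the integrin subunit Itgb8 (-1.26), with adjusted p from 0.000326 to 0.0364. With limma, 571 of 13555 genes passed (204 up, 367 down; 521 of them protein-coding). The count was 376 with no filter on low values, 972 against PP replicates 3 and 11 alone, and 2325 against PP replicates 9 and 10 alone. Both pairs were picked for their close correlation, so the counts against them are biased upward. It was 379 without PP replicate 3, 199 without PP replicate 9, 233 without QPP replicate 12, 250 without QPP replicate 1, 221 without QPP replicate 7 and 189 without QPP replicate 8. Brsk2 lost its call without each library except PP replicate 10 (adjusted p from 0.0572 to 0.10) and Itgb8 without each except PP replicate 11 (from 0.0524 to 0.108). Tub lost it without PP replicate 9 (0.0591) or QPP replicate 1 (0.0558), Azin2 without QPP replicates 1 (0.0522) or 7 (0.0591), Pnp2 without PP replicate 9 (0.0675) or QPP replicates 12 (0.0569) or 8 (0.0563), and Nucb2 (0.0519) and Sspn (0.0538) without QPP replicate 8. Against PP replicates 3 and 11 alone Tub (0.0532), Pnp2 (0.0625) and Brsk2 (0.0574) did not pass.

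Lysosomal genes were mostly lower and cholesterol synthesis genes mostly higher in QPP than in PP, by sizes that differed between the PP libraries. Of 60 lysosomal genes measured, 9 fell and 0 rose over all genes tested, and 18 fell and 1 rose when adjusted over the list alone, with a median log2 change of -0.292 (50 below 0; camera adjusted p = 2.42e-07, and adjusted p = 0.926 with an estimated correlation). They included Cln5 (-0.99 ± 0.12, adjusted p = 0.00546), Galc, the galactosylceramidase (-0.93 ± 0.17, 0.0235), Lamp1, a lysosomal membrane protein (-0.66 ± 0.12, 0.0205), and Gusb, the beta-glucuronidase (-0.56 ± 0.09, 0.0173). Of 23 cholesterol synthesis genes, 2 rose and 0 fell (10 rose and 0 fell when adjusted over the list alone; median 0.335; camera adjusted p = 2.8e-07, and adjusted p = 0.926 with an estimated correlation): Acat2 (0.67 ± 0.13, adjusted p = 0.0326) and the mevalonate pathway kinase Pmvk (0.52 ± 0.11, 0.0449). Acat2 lies within 20 Mb of the floxed Qk gene. With fry, which asks for a shift on balance in 1 direction, both lists stood at adjusted p = 0.20. Correlations between libraries were taken across protein-coding genes with a mean of at least 1 FPKM. The PP libraries correlated as 2 pairs, 0.989 between replicates 9 and 10 and 0.991 between replicates 3 and 11. Between replicates 10 and 11 the correlation was 0.949, below the 0.984 between PP replicate 11 and QPP replicate 8. Against PP replicates 3 and 11 alone the lysosome median was -0.0789 (camera adjusted p = 0.157) and the cholesterol median 0.187 (0.032). Against PP replicates 9 and 10 alone they were -0.51 (2.12e-12) and 0.483 (8.81e-10), a division chosen after the data were seen. The pairs were picked for their close correlation, so p-values against either pair are biased low. With an estimated correlation no list passed against either pair (lowest adjusted p = 0.421 with an estimated correlation for replicates 3 and 11, and 0.729 for 9 and 10). Fry put the lysosome, cholesterol, endosome and RNA-binding lists at adjusted p = 0.0226 against replicates 9 and 10 alone. Against replicates 3 and 11 alone fry had the lysosome and cholesterol lists at adjusted p = 0.385 and the neural stem cell list at 0.0159.

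The other 3 lists that camera called were also lower in QPP. Of 46 endosome and receptor trafficking genes, 2 fell over all genes tested, Cav2, a caveolin (-0.61 ± 0.10, adjusted p = 0.0173), and the small GTPase Rab5a (-0.59 ± 0.10, 0.0193), and 10 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0186, and adjusted p = 0.926 with an estimated correlation). Of 23 fatty acid and PPAR genes, 1 fell, the desaturase Scd1 (-0.64 ± 0.09, adjusted p = 0.00871), and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0186, and adjusted p = 0.926 with an estimated correlation). Of 20 interferon response genes limma passed 0, also when adjusted over the list alone (1 at an unadjusted p under 0.05), but 19 were below 0, with a median of -0.599 (camera adjusted p = 0.0264, and adjusted p = 0.948 with an estimated correlation). Against PP replicates 3 and 11 alone the endosome median was -0.0439 (camera adjusted p = 0.411), the fatty acid median -0.092 (0.395) and the interferon median -0.0193 (0.959). Against PP replicates 9 and 10 alone they were -0.189, -0.381 and -1.31. Without PP replicate 10 the endosome list was at 0.0618, the fatty acid list at 0.0779 and the interferon list at 0.229. The interferon list also lost its call without PP replicate 9 (0.157) and without QPP replicates 12 (0.0871), 7 (0.0836) and 8 (0.131).

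Single members passed in 8 of the 17 lists that camera did not call in PM-NSC. Of 28 receptors of stem cell signalling, the Wnt receptor Fzd9 rose (1.08 ± 0.22, adjusted p = 0.0364) and Fzd3 (-0.40, 0.0288) and Bmpr2 (-0.36, 0.0447) fell, and 2 rose and 3 fell when adjusted over the list alone. Of 20 neural stem cell markers Fabp7 rose (0.63, adjusted p = 0.0413), and 2 rose when adjusted over the list alone. Of 13 astrocyte markers Mlc1 fell, and 1 rose and 1 fell when adjusted over the list alone. Of 6 myelinating oligodendrocyte markers Ugt8a, a galactolipid-synthesis enzyme, rose (0.95 ± 0.12, 0.00791), and of 9 neuron markers the synaptic gene Snap25 rose (1.15 ± 0.19, 0.0172). Of 11 proneural glioblastoma genes Dbn1 rose (0.47, adjusted p = 0.0338; 4 when adjusted over the list alone; camera 0.0648). Of 17 RNA-binding and splicing genes Rbfox2 (0.59 ± 0.09, adjusted p = 0.0115) and Ptbp2 (0.52 ± 0.11, 0.0364) rose, both splicing regulators, and of 17 reported QKI splicing targets Map4k4 fell (-0.44 ± 0.06, 0.00949). Limma passed 0 members among 8 oligodendrocyte precursor, 5 fibroblast, 22 p53 target, 30 cell cycle, 18 extracellular matrix, 17 PI3K-AKT, 5 sex-linked, 29 ribosomal protein and 12 housekeeping genes, also when adjusted over the list alone (9 of these 146 were at an unadjusted p under 0.05), and camera gave these 9 lists adjusted p from 0.112 to 0.979. Of the lists not called, leaving out PP replicate 10 called the neural stem cell (0.0479), cell cycle (0.0321), proneural (0.00987) and housekeeping (0.0479) lists. Leaving out PP replicate 9 called the neural stem cell (0.0417) and proneural (0.0417) lists, QPP replicate 12 the matrix list (0.00827) and QPP replicate 8 the proneural list (0.0224). Against PP replicates 3 and 11 alone the astrocyte list was called up (0.032) and the cell cycle list down (4.45e-05), and against PP replicates 9 and 10 alone the astrocyte list was called down (0.0402) and the cell cycle list up (0.00969). The neural stem cell (0.00376), proneural (0.00376), myelinating oligodendrocyte (0.0344) and matrix (0.0205) lists were called against the first pair and the RNA-binding list (0.00469) against the second, none of them with an estimated correlation. Median and mean differed in sign for the myelinating (-0.0867 and 0.0636), neuron (-0.0251 and 0.0642), p53 target (0.0324 and -0.00596) and PI3K-AKT (-0.0239 and 0.0116) lists, and camera had the precursor list up at a median of -0.133. The ribosomal protein list turned to a called shift the other way, adjusted p = 2.25e-06, when the libraries were quantile-scaled. Lists with under 5 measured members were read by member. Foxj1, a regulator of motile cilia, fell (-0.54 ± 0.12, adjusted p = 0.0449), and the choroid plexus gene Ttr (1.02, 0.0736), the macrophage genes Cd14 (0.50, 0.227) and Cd68 (-0.24, 0.48), the mural gene Acta2 (0.48, 0.187) and the T cell gene Trbc2 (-0.97, 0.61) did not pass.

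**Figure D2:**
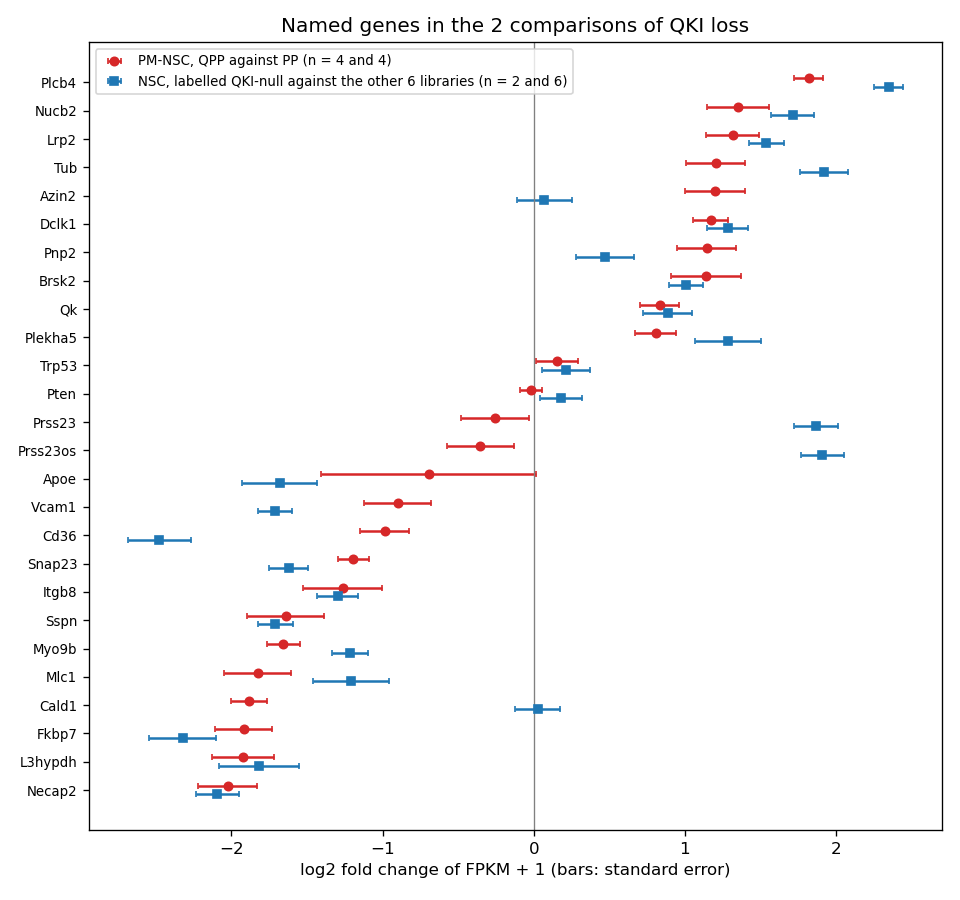
Log2 change, with its SE, of the genes named by the rule and measured in both systems, in PM-NSC (QPP against PP) and in NSC (labelled QKI-null against the other 6 libraries). Plcb4 is 1.82 in PM-NSC and 2.35 in NSC, and Cald1 is -1.88 in PM-NSC and 0.03 in NSC.

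In NSC, where Pten and p53 are not targeted per the labels, the question was what differs once 4OHT has acted on the floxed Qk allele. The 2 labelled QKI-null libraries had 4OHT and most of the 6 others EtOH, so their contrast carries part of any 4OHT effect. Plcb4 rose by a log2 change of 2.35 ± 0.10 (SE) in the 2 labelled QKI-null libraries against the 6 others (adjusted p = 7.15e-05), Tub by 1.92 ± 0.16 (0.00214), and Lrp2, the endocytic receptor megalin, by 1.54 ± 0.12 (0.00146). The fatty acid scavenger receptor Cd36 fell by 2.48 ± 0.21 (adjusted p = 0.00252) and stood at 2.02 ± 0.268 FPKM (SD, n = 2), against 18.4 and 19.7 in the wild-type groups and 11.4 in floxed cultures with EtOH. Necap2 fell by 2.09 ± 0.14 (adjusted p = 0.000886), and the adhesion molecule Vcam1 fell by 1.71 ± 0.11 (0.000705). The lipid carrier Apoe fell by 1.68 ± 0.25 (0.0222), to 86.1 FPKM from 408, 292 and 187 in the control groups. The other risen genes named by the rule were Prss23os (1.91), Prss23 (1.87), Sostdc1 (1.83), Nucb2 (1.71) and Plekha5 (1.28), and the other fallen ones were Fkbp7 (-2.32), L3hypdh (-1.82), Sspn (-1.71) and Snap23 (-1.62), with adjusted p from 0.000886 to 0.0344. Prss23 and Prss23os overlap on opposite strands, and the labels do not say whether the libraries were stranded. With limma, 279 of 14077 genes passed (124 up, 155 down), and 250 of them were protein-coding. Quantile scaling gave 1457, the culture as a random effect 416, no filter on low values 124, and 4OHT-treated wild type alone as the reference 156. The count was 26 and 30 without labelled QKI-null cultures 3 and 5, 687 and 513 without floxed EtOH cultures 3 and 5, 139 and 130 without wild-type 4OHT cultures 2 and 9, and 134 and 176 without wild-type EtOH cultures 2 and 9. Leaving out QKI-null cultures 3 or 5 ended the calls of Sostdc1 (adjusted p = 0.12 and 0.233), Plekha5 (0.272 and 0.178), L3hypdh (0.187 and 0.132) and Apoe (0.225 and 0.151), and a pseudocount of 0.1 that of Sostdc1 (0.0635). Leaving out wild-type EtOH culture 2 or floxed EtOH culture 5 ended that of Plekha5 (0.0617 and 0.0523).

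In the labelled QKI-null NSC most astrocyte markers were lower and most neuron markers higher, few of them past the threshold. Of 13 astrocyte markers 1 fell, the intermediate filament gene Gfap (-1.75 ± 0.29, adjusted p = 0.0324), and 3 fell when adjusted over the list alone (median -0.368, camera adjusted p = 0.00317, and adjusted p = 0.62 with an estimated correlation). Gfap was also lower with 4OHT in wild-type cultures in the fit with the culture block, so part of its fall here may come with 4OHT. Of 6 neuron markers 1 rose, Snap25 (0.86 ± 0.13, 0.0276), and 3 rose when adjusted over the list alone (5 of 6 above 0; camera 0.00882, and adjusted p = 0.62 with an estimated correlation). All 11 proneural glioblastoma genes were above 0, with a median of 0.452, and limma passed 0 over all genes (6 at an unadjusted p under 0.05) and 4 when adjusted over the list alone (camera 8.7e-05, and adjusted p = 0.62 with an estimated correlation). Of 60 lysosomal genes Galc (-0.97 ± 0.12, 0.0111) and Npc1 (-0.73, 0.0414), a lysosomal cholesterol transporter, fell, and 4 fell when adjusted over the list alone (camera 0.00038, and adjusted p = 0.934 with an estimated correlation). Of 23 fatty acid and PPAR genes Scd1 (-0.89 ± 0.15, 0.0324) and Acadl (-0.78, 0.0389) fell, and 4 when adjusted over the list alone (camera 8.7e-05, and adjusted p = 0.934 with an estimated correlation). Of 14 extracellular matrix genes the fibronectin gene Fn1 fell (-0.99 ± 0.15, 0.0256), and 2 when adjusted over the list alone (camera 0.00527, and adjusted p = 0.62 with an estimated correlation). Of 30 cell cycle genes limma passed 0, also when adjusted over the list alone (4 at an unadjusted p under 0.05), with a median of -0.0682 (camera 0.0226, and adjusted p = 0.934 with an estimated correlation). The astrocyte call ended with quantile scaling (0.0558) and without QKI-null culture 3 (0.124), the matrix call without floxed EtOH culture 5 (0.0545), and the cell cycle call without wild-type 4OHT culture 2 (0.0702), wild-type EtOH culture 9 (0.0683) or QKI-null culture 5 (0.421).

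Of 20 neural stem cell markers measured in NSC, a list that camera did not call, 11 were above 0 (median 0.00557) and 3 fell. The glutamate transporter gene Slc1a3 fell by 1.26 ± 0.15 (adjusted p = 0.0111), Cd44 by 0.99 (0.0225) and Prom1 by 0.87 (0.0422), and the same 3 counted as fallen when adjusted over the list alone. The receptor gene Fgfr3 (-0.77, adjusted p = 0.0475), the oligodendrocyte gene Aspa (-0.91, 0.0443), the p53 target Pmaip1 (-0.60, 0.0343) and the cilia genes Foxj1 (-0.90, 0.0177) and Rsph1 (-0.67, 0.0361) fell, and Rbfox2 rose (1.03 ± 0.11, 0.00661). The mural genes Acta2 (-1.30, 0.189) and Tagln (-1.24, 0.114) did not pass. In NSC, limma passed 0 of 23 cholesterol synthesis genes, also when adjusted over the list alone (1 at an unadjusted p under 0.05), and 0 of 46 endosome genes (8 at an unadjusted p under 0.05), of which 3 fell when adjusted over the list alone. The 5 sex-linked control genes had a median of 1.44, with the Y-linked Ddx3y at 2.11 ± 1.5 (adjusted p = 0.555) and Xist at -1.54 ± 1.32 (0.638), and camera did not call the list (adjusted p = 0.5) but did without QKI-null culture 3 (0.0094). Without QKI-null culture 5 it called the receptor (0.0324) and oligodendrocyte precursor (0.0347) lists as well.

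Within floxed cultures alone, the libraries with 4OHT were set against those with EtOH. Plcb4 rose by 2.39 ± 0.12 (SE, n = 2 per group, adjusted p = 0.000219), Lrp2 by 1.82 (0.00396) and Nucb2 by 1.82 (0.0107). Necap2 fell by 2.07 ± 0.18 (adjusted p = 0.00545) and L3hypdh by 2.35 (0.0462). Tub (1.91), Prss23os (1.44), Prss23 (1.38), the GABA receptor subunit gene Gabra4 (1.36) and Dclk1 (1.32) also rose, and Fkbp7 (-2.15), Cd36 (-1.98), Snap23 (-1.49), Vcam1 (-1.39) and Myo9b (-1.07) also fell. Qk itself was at 1.02 ± 0.20 with adjusted p = 0.118, and at adjusted p = 0.0048 when the cultures were paired by a block. With limma, 35 of 14077 genes passed (22 up, 13 down; 26 protein-coding), and 617 (441 up, 176 down; 421 protein-coding) with the culture numbers as a block. Quantile scaling, which moved the median of all genes by 0.132 in this contrast, gave 94 up and 139 down. With the block as well it gave 35 up and 71 down, so the balance of directions rests on the scaling. Floxed EtOH culture 5 had a median log2 level of 3.22 over measured protein-coding genes, against 3.54 in floxed EtOH culture 3. The median change of all genes was -0.02 without the first of these libraries and 0.292 without the second. The count was 9 without QKI-null culture 3, 9 without culture 5, 17 without floxed EtOH culture 5 and 13 with no filter on low values. Camera called the astrocyte (adjusted p = 0.00325, with the block 0.000296) and fatty acid (0.000251, 0.000765) lists down and the neuron (0.026, 0.00906) and proneural (0.000251, 3.65e-05) lists up, and none held with an estimated correlation (lowest adjusted p = 0.891 with an estimated correlation). It also placed the cell cycle list below other genes (0.0178, with the block 0.0297, and adjusted p = 0.891 with an estimated correlation), but 17 of its 30 genes were above 0 (median 0.022, mean -0.0229), so the list itself was not lower. The lysosome list, called down against the other 6 libraries, was not called by camera here (adjusted p = 0.0524, with the block 0.0618). Of its 60 genes 37 were above 0, with a median of 0.0846 where that of all genes was 0.132. Camera did not call the matrix list here either (0.153, with the block 0.122). Fry for change in either direction called 5 lists, and 0 with the block. Among the members of the called lists, limma with the block passed 3 proneural and 2 neuron genes up and 2 astrocyte and 2 fatty acid genes down, against 0 of each without it.

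In wild-type NSC without the block, the genes passing between 4OHT and EtOH were all small RNAs. Of 8 genes passing (3 up, 5 down), 4 were small nucleolar, 2 micro, 1 small nuclear and 1 ribosomal RNA. The small nucleolar RNA Snord35b was 44.75 and 47.25 FPKM in the 2 wild-type libraries with 4OHT and listed at 0 in the others. The 5S ribosomal RNA n-R5s197 was listed at 0 in all 4 libraries with 4OHT and at 4.08 to 7.09 in all 4 with EtOH. Qk was at log2 -0.04 ± 0.20 (SE, n = 2 per group). Limma passed 0 genes among protein-coding genes tested alone, where 56 were at an unadjusted p under 0.05. With the block 87 passed (45 up, 42 down), 10 of them protein-coding, among them the astrocyte gene Gfap (-0.77, adjusted p = 0.0422 with the block). The count of 8 was 13 with no filter on low values, 5 with a pseudocount of 0.1, 1 with a minimum of 5 FPKM, 4 (2 up, 2 down) with quantile scaling, 2 and 5 without wild-type 4OHT cultures 2 and 9, and 16 without either QKI-null culture, which enter through the pooled spread and the filter on low values. Camera called the lysosome list up (adjusted p = 0.000869, with the block 0.00904), the neural stem cell list down (0.00903, 0.0356) and the cell cycle list down (0.0131, 0.0809 with the block, which ends that call), all at adjusted p = 0.982 with an estimated correlation.

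The change with 4OHT differed between floxed and wild-type NSC for 10 genes (7 up, 3 down). Plcb4 differed by a log2 change of 2.22 (adjusted p = 0.00286) and Necap2 by -2.25 (0.0316), and Lrp2, singled out after its value was seen, by 1.96 (0.0196). These 3 were the protein-coding ones. The other 7 were small RNAs, such as Snord45c, at 244.2 and 193.6 FPKM in the labelled QKI-null libraries and listed at 0 elsewhere. Limma with the block gave 211 (124 up, 87 down; 82 protein-coding). Quantile scaling, which moved the median of all genes by 0.111 here, gave 16 (9 up, 7 down), block and quantile scaling together gave 7, and protein-coding genes tested alone gave 1. The count was 6 without wild-type 4OHT culture 2 and 17 without floxed EtOH culture 3. Camera called the lysosome, astrocyte and fatty acid lists down and the neuron and proneural lists up, with and without the block. It called the interferon list down with the block alone (adjusted p = 0.0351, 0.0748 without it). The lowest adjusted p was 0.904 with an estimated correlation and 0.945 with block and estimated correlation. The lysosome median was -0.0471 (25 of 60 genes above 0). With 4OHT that list's median was 0.0846 in floxed and 0.119 in wild-type cultures, so its call does not rest on a fall in floxed cultures.

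The 2 cell systems shared more changed genes than their numbers would give by chance. Among 12821 genes tested in both, 25 rose in both (184 and 116 rose in PM-NSC and NSC, 1.66 expected) and 66 fell in both (361 and 141 fell, 3.97 expected). In opposite directions there were 0 and 0 genes, where 2.02 and 3.27 were expected. The shared genes included Plcb4, Tub, Nucb2, Dclk1, Rbfox2 and Snap25 among those up, and Necap2, Fkbp7, L3hypdh, Sspn, Cd36, Scd1, Galc and Foxj1 among those down. Across genes, which are not independent replicates, the log2 changes of the 2 systems correlated with r = 0.303 and rho = 0.42. Of the 545 genes passing in PM-NSC, 91.2% had the same sign in NSC, and of the 257 passing in NSC, 82.9% had the same sign in PM-NSC.

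For 21 genes the change itself differed between the systems (5 higher and 16 lower in PM-NSC). Cald1 fell in PM-NSC (-1.88) and was at 0.03 in NSC, a difference of -1.91 ± 0.19 (adjusted p = 0.000303). Prss23 was at -0.26 in PM-NSC and rose in NSC (1.87), a difference of -2.12 ± 0.30 (0.00824), and its antisense gene Prss23os differed by -2.26 ± 0.29 (0.00419). Trim47 was at 0.94 in PM-NSC and -0.58 in NSC, a difference of 1.52 ± 0.16 (0.000599). Singled out after their values were seen, Dbndd2 (1.29), Tmeff2 (-1.0), Thsd7a (-0.95), Pde9a (-0.93) and Cobll1 (0.88) also differed, with adjusted p from 0.00872 to 0.0472. Of the 21, 8 were protein-coding, 1 was antisense, 9 were pseudogenes, which can share reads with their parent genes, and 3 were small RNAs. The count in limma was 13 with a minimum of 5 FPKM, 37 with quantile scaling (13 up, 24 down), and 9 without QKI-null culture 3 or 5.

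Transcript proportions changed in many genes in the libraries labelled QKI-null. In Map2, a microtubule-associated protein gene (chromosome 1, 66251662 to 66442581), ENSMUST00000114018 made up 81.9% ± 1.65 of the gene's FPKM in PP (SD, n = 4) and 16% ± 2.64 in QPP, while ENSMUST00000024639 reached 56.3% ± 2.67 in QPP. In NSC the first of these stood at 83.4%, 83.1% and 83.4% in the control groups and 9.4% ± 3.55 (SD, n = 2) in the labelled QKI-null cultures. In Gpm6b, a proteolipid gene of neural membranes (chromosome X, 166238972 to 166388988), ENSMUST00000060210 went from 9.91% ± 1.99 to 74.1% ± 1.93 in PM-NSC and, from at most 4.12% in the NSC control groups, to 67.4% ± 0.513. In Dock7, ENSMUST00000075836 went from 40.7% ± 1.78 in PP to 0.00352% in QPP. In the tropomyosin gene Tpm1, ENSMUST00000113696 went from 11.7% ± 4.11 to 62.9% ± 2.31 in PM-NSC and, from at most 4.97%, to 52.9% ± 1.63 in NSC. Limma's transcript-level test (diffSplice with Simes) passed 320 of 3630 genes in PM-NSC, with the lowest adjusted p for Gpm6b (1.41e-30), Map2 (1.24e-22), Map4k4 (3.2e-22), Csnk1a1 (8.27e-21) and Dock7 (2.55e-20). In NSC it passed 275 of 3829 genes, led by Gpm6b (3.4e-22), Sptan1 (5.98e-14), Myo18a (1.99e-13), Tpm1 (1.99e-13) and Phldb1 (2.34e-13). With a minimum of 5 FPKM the counts were 135 and 150, and without QKI-null cultures 3 or 5 the NSC count was 148 or 140.

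Of 11 reported QKI splicing targets tested for transcript proportions, 8 passed in PM-NSC (0.97 expected from 320 of 3630 genes; Fisher's exact test, two-sided, p = 4.37e-07) and 7 in NSC (0.79 expected; p = 2.35e-06). Those that passed in both systems were Map4k4, Capzb, Add3, Macf1, Bin1, Cttn and Sorbs1, with Fgfr1 (adjusted p = 0.0213) passing in PM-NSC. In Sorbs1, a cytoskeletal adaptor gene, ENSMUST00000099466 went from 25.8% ± 7.6 in PP to 76.3% ± 3.72 in QPP (SD, n = 4 each; adjusted p = 0.000121) and reached 80.8% ± 4.4 in labelled QKI-null NSC, from 22.6% to 27.8% in the control groups (7.37e-08). In Capzb, an actin-capping subunit gene, ENSMUST00000102507 went from 38.6% ± 10.3 to 1.21% ± 0.197 in PM-NSC (9.78e-15) and to 0.217% ± 0.162 in NSC (4.22e-07). In Macf1, a microtubule-actin linker gene, ENSMUST00000082108 went from 43.4% ± 3.11 to 81.6% ± 0.975 in PM-NSC (1.22e-09) and to 68.5% ± 0.768 in NSC (0.00296). In the cortactin gene Cttn, ENSMUST00000103079 went from 3.92% ± 1.82 to 21.9% ± 3.38 in PM-NSC (5.93e-05) and to 27.5% ± 0.133 in NSC (2.84e-07). Add3 (4.17e-10 in PM-NSC, 1.41e-07 in NSC) and Bin1 (5.23e-06 and 1.18e-05) passed as well. Among 3203 genes tested in both systems, 168 passed in both (304 in PM-NSC, 248 in NSC, 23.54 expected), and of 162 whose leading transcript could be compared, 161 moved in the same direction.

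**Figure D3:**
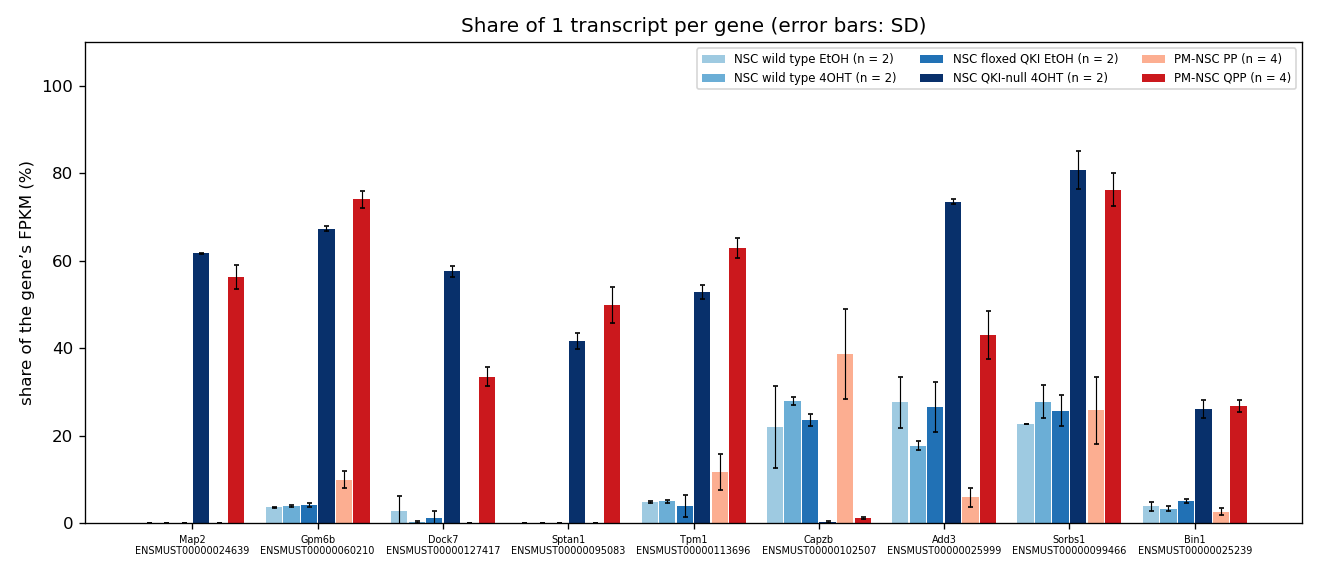
Share of the gene's FPKM, in percent, taken by 1 transcript of each of 9 genes, as bars of group means with SD (n = 2 per NSC group, n = 4 per PM-NSC group). ENSMUST00000060210 of Gpm6b averages 9.91% in PP and 74.1% in QPP, and ENSMUST00000099466 of Sorbs1 averages 25.8% and 76.3%.

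Oligodendrocyte-lineage lists had the highest mean levels of the cell type lists in the tumors, which have no control group. A list's mean level depends on which genes it holds, so this order gives no share of cell types. Across 16 tumors, the myelin genes Mbp and Plp1 had medians of 530 FPKM (21.6 to 1380) and 279 (16.6 to 572), and the lineage factors Olig1 and Olig2 109 (6.06 to 181) and 74.3. The receptor gene Pdgfra had a median of 77 and ranged from 2.08 to 780. The proliferation gene Top2a had a median of 42.5 (0.795 to 84), the astrocyte gene Gfap 40.2 (2.57 to 424), and the macrophage complement gene C1qa 58.4 (17.3 to 171). Qk had a median of 238 FPKM (67.2 to 410), Pten 9.58 (6.92 to 13.0) and Trp53 1.5 (1.11 to 2.73). As mean log2 levels per list, the myelinating oligodendrocyte list had a median of 5.10 (2.53 to 6.21) and the oligodendrocyte precursor list 4.90. Lower lists included cell cycle at 3.86, neural stem cell at 3.14, microglia and macrophage at 2.97, astrocyte at 2.60 and endothelial and mural at 1.96. Neuron stood at 1.91, fibroblast at 1.59, ependymal at 0.25 and T cell and granulocyte at 0.18. The erythroid list, at 4.42, ranged from 1.37 to 7.15, and the hemoglobin gene Hbb-bs from 3.43 to 1270 FPKM. Tumor TKO-tumor_RNA25_13143 stood apart, with a median correlation of 0.654 with the other tumors (0.886 to 0.933 for the rest), the lowest precursor (1.77) and cell cycle (1.30) scores and the highest astrocyte (5.29) and neuron (4.48) scores.

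Lysosomal gene levels followed microglia and macrophage marker levels across tumors. The correlation was r = 0.874 over 16 tumors (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 0.00012 over 12 relations) and rho = 0.929 (adjusted p = 0.00012). It was r = 0.86 without the 2 tumors farthest from the median. The lysosome list was not cleared of genes that microglia and macrophages themselves express, so the 2 scores are not independent measures. The other 11 relations did not pass. The nearest were Qk with the neuron list (r = -0.711, adjusted p = 0.0679), cell cycle with the neuron list (-0.771, 0.0679), the precursor list with the matrix list (0.552, 0.0682) and cell cycle with the neural stem cell list (0.53, 0.0754). Without the tumor TKO-tumor_RNA25_13143 these neuron relations were at -0.231 and -0.175 and the precursor-matrix relation at 0.147, so they rest on that tumor. With scores built from z-values 4 relations passed instead of 1, adding Qk with neuron (0.031), cell cycle with neuron (0.0445) and cell cycle with neural stem cell (0.0445).

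**Figure D4:**
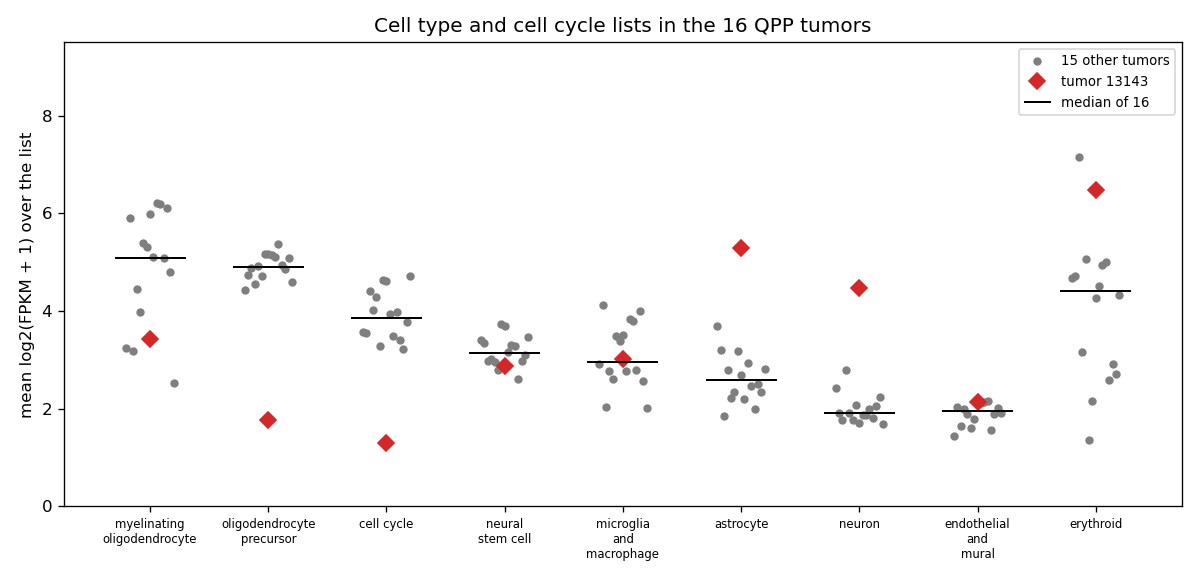
Mean log2 level of each marker list in each of the 16 tumors, with the median marked. The myelinating oligodendrocyte list has a median of 5.10, and the tumor that stands apart has the lowest cell cycle score, 1.30, and the highest neuron score, 4.48.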

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

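The counts of genes, of transcript changes and of called lists over other splits of the PM-NSC libraries, the splits of the endosome, fatty acid and interferon lists, the comparison with each pair of PP libraries and the test of Qk under 4OHT in wild type were chosen only after the result was seen.

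A single library far from its group was looked for in 80 groups of 4 values, and 2 were found where about 4 are expected by chance, since chance gives 5 in 100. Map4k4 was 91.9 FPKM in QPP replicate 1, against 86.0 to 86.7 in the other 3. Ptbp2 was 38.7 FPKM in QPP replicate 12, against 34.4 to 34.8 in the other 3.

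The change in libraries labelled QKI-null differed between PM-NSC and NSC for 21 genes by a test of the difference, among them Cald1 (-1.91), Prss23os (-2.26) and Prss23 (-2.12). The change with 4OHT differed between floxed and wild-type NSC for 10 genes, among them Plcb4 (2.22) and Necap2 (-2.25).

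The Qk gene level was higher in the libraries labelled QKI-null, in PM-NSC and in NSC. Scaling of the libraries as the whole cause is argued against, since the PM-NSC log2 change was 0.77 after quantile scaling. An action of 4OHT itself on Qk is argued against by the wild-type cultures, where the log2 change with 4OHT was -0.04. What stays open, as a hypothesis, is a change in Qk RNA after recombination. The higher level may follow the fall of the transcript ENSMUST00000042296. No test here separates that from an effect of reads around the deleted exon on the assembly.

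In PM-NSC, the 571 genes and the 320 genes with changed transcript proportions were each reached by 1 of the 35 splits of the 8 libraries. That was the real one, with 60 and 16 as the highest of the others, which argues against chance for these counts. It does not exclude chance, since 1 of 35 is the smallest share these splits can give. Nor do the splits test a difference between the PP cultures themselves.

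For the 5 lists that camera called in PM-NSC chance cannot be excluded, since 24 of 35 splits called as many and the highest other called 11. As far from 0 as the real median went 2 of 35 splits for the lysosome list (real -0.292, highest other 0.337) and 2 for cholesterol synthesis (0.335, 0.35). For endosome 8 did (-0.065, 0.163), for interferon 9 (-0.599, 1.356) and for fatty acid 1, the real one (-0.24, 0.231). The exact p adjusted over the 5 lists was 0.0952 for the lysosome, cholesterol and fatty acid lists and 0.257 for the others. Chance is not excluded for any of the 5. The smallest exact p that 35 splits can give is 0.0286, that of the fatty acid list, so 1 list alone could not pass this adjustment. Among the other splits the lysosome median was -0.337 to -0.145 in the 14 that kept PP replicates 9 and 10 on 1 side and -0.122 to 0.053 in the 20 that parted them, and the cholesterol median 0.108 to 0.35 and -0.143 to 0.161. Scaling as the cause of the lysosome shift is argued against, since its median was -0.291 after quantile scaling. A difference between the PP cultures themselves is a candidate explanation for much of these shifts and stays open, since the lysosome median was -0.0789 against replicates 3 and 11 and -0.51 against replicates 9 and 10, and no other PP libraries are there to test it on.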

How the results depend on the processing

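Each pair of PP libraries alone, the block with quantile scaling, protein-coding genes alone and tumors without TKO-tumor_RNA25_13143 were chosen only after the data were seen. Leaving out 1 library at a time gave 189 to 499 genes in PM-NSC, 26 to 687 in NSC, 9 to 50 in floxed NSC with 4OHT, 2 to 16 in wild-type NSC, 6 to 17 for the difference of these, 9 to 28 for PM-NSC against NSC, 262 to 332 and 140 to 322 genes with changed transcript proportions in PM-NSC and NSC, and 4 to 6 and 6 to 8 called lists. With 1 library left in an arm, limma assumes it to vary like the other groups. With no filter on low values the counts were 376 in PM-NSC, 124 in NSC, 13 in floxed and 13 in wild-type NSC. With quantile scaling they were 1457 in NSC, 233 in floxed NSC, 4 in wild-type NSC, 16 for their difference and 37 for PM-NSC against NSC. With the block they were 617, 87 and 211 in floxed NSC, wild-type NSC and their difference, and 106 in floxed NSC with block and quantile scaling. A minimum of 5 FPKM gave 1 in wild-type NSC, 13 for PM-NSC against NSC, and 135 and 150 genes with changed transcript proportions. A pseudocount of 0.1 gave 5 in wild-type NSC, protein-coding genes alone gave 0 there (56 at an unadjusted p under 0.05 in limma) and 1 for the difference, and 4OHT-treated wild type alone as the reference gave 156 in NSC. An estimated correlation left 0 called lists in PM-NSC and 0 in NSC, and z-scored lists gave 4 tumor relations. Against PP replicates 3 and 11 alone PM-NSC gave 972 genes, and against 9 and 10 alone 2325 genes and 8 called lists. Each pair holds fewer libraries and was picked for its closeness, which biases these counts upward. The astrocyte list (adjusted p = 0.032) reversed against the first pair and the cell cycle list (0.00969) against the second, none called with an estimated correlation. Against the first pair the interferon median stayed below 0 (-0.0193), while camera placed the list above other genes at adjusted p = 0.959. The ribosomal protein list in PM-NSC reversed to a called shift (adjusted p = 2.25e-06) with quantile scaling. The cause was not tested. Of the 16 genes the rule named by size in PM-NSC and the 16 in NSC against the other 6 libraries, 223 results without 1 library stayed past the threshold and 33 did not, and under the pseudocount, scaling, random-effect and PP-pair settings 108 did and 4 did not, with none of these reversed. Genes named by size in the 4OHT comparisons were followed under the block alone, and those named for the difference between PM-NSC and NSC or as list members under none of the settings. Among camera's list calls the block changed none besides those given. Depth limits what small changes can be seen, and the files do not give it.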

Other observations

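The correlations without the tumor TKO-tumor_RNA25_13143 and the counts of small RNAs at 0 between pairs of libraries were chosen only after the result was seen.

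Among genes with a median of at least 5 FPKM, the spread between tumors was largest for the noncoding RNAs Rn7sk (SD of log2 4.26, listed at 0 in tumor TKO-tumor_RNA25_14197) and Rprl3 (3.38). Of the other genes named by their spread, Hbb-bs (2.22), Hba-a1 (2.10), Hba-a2 (2.08) and Hbb-bt (2.08) encode hemoglobin chains, Mobp (2.11, from 0.0999 to 115 FPKM) a myelin protein, and Ndn (2.02, from 0.0381 to 103 FPKM) is imprinted. Oligodendrocyte precursor genes stood at medians of 72.6 FPKM (Gpr17), 59.2 (Sox10) and 52.3 (Sox8), the neural genes Map2 and Dcx at 73.2 and 23.1, and the lysosomal genes Psap and Ctsd at 168 and 108. The interferon list had a median of 1.12 (0.69 to 3.0).

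For each pair of libraries, small RNAs at 1 FPKM or more in at least 1 of them were taken, from 715 tested in NSC and 618 in PM-NSC. Those listed at 0 in the other library averaged 23.1% within pairs of the same NSC group and 23.7% between groups. In PM-NSC the averages were 10.1% and 10.3%, against at most 0.1% for protein-coding genes.

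In the tumors the transcript ENSMUST00000042296 averaged 8.79% ± 4.58 of Qk FPKM (SD, n = 16, from 4.14% to 23.6%). Besides Qk, 167 genes were called for transcript proportions in both PM-NSC and NSC. Of these, 149 had shares that differed by 5 points or more between PP and QPP and could be read in every tumor. For 114 of the 149 (76.5%) the tumor median lay nearer the QPP mean, which the hypothesis of recombined Qk in most tumor cells predicts. The count does not decide it, since no tissue with intact Qk was measured. Tumor TKO-tumor_RNA25_13143, which stood apart, also had 94 of the 149 nearer the QPP mean. Under the hypothesis that unrecombined cells carry the remaining transcript, its share might follow markers of other cell types, but rho was -0.174 with the myelin list, 0.397 with neuron, -0.05 with microglia and -0.241 with endothelial markers, none past the threshold over 4 relations, and permutations of 16 tumors give values as far from 0, so these cannot be told apart. With neuron, r was 0.851 (adjusted p = 0.0322) and 0.324 without tumor TKO-tumor_RNA25_13143, so it rests on that tumor.

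Tumor TKO-tumor_RNA25_13143 had the highest neuron score. Scaling is argued against, since after quantile scaling its neuron score was 5.27 and the next highest 3.64. A larger part of normal brain tissue in this tumor is a candidate explanation. It predicts a higher share of ENSMUST00000042296, if normal brain has as much of it as the control cultures. The share was 23.6% there and at most 11.4% in the other tumors. No normal brain was measured, so its own share is unknown and the prediction cannot decide the question. Over the switched transcripts this tumor lay 83.9% of the way from PP to QPP, the next lowest tumor 89.4%, so it too lay nearer QPP. The abundant neuron gene Snap25 ranged up to 1290 FPKM, while Dcx was 0.282, Gpr17 0.629, Olig2 1.86 and Top2a 0.795 FPKM in this tumor. The labels give no region, so a tumor of another type stays open.

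Sequence linked to the floxed Qk allele was put forward as a source of the called genes. As a source of the set it is argued against, since 7 of 570 called genes lay within 20 Mb of Qk in PM-NSC against 260 of 13554 tested, 0.64 times their share, and in NSC the ratio was 0.393. For single genes within that distance, such as Acat2, it stays open.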
